A study of Homo sapiens with 24 samples.

How the data were processed

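Poly(A) RNA of 24 cultures of HepG2 cells was sequenced, in 6 groups of 4 biological replicates formed by 3 receptor genotypes and 2 treatments. Per the labels' protocols, expression of the receptor was induced with 0.3 to 1 µg/mL doxycycline for 24 h at doses that matched receptor protein, hormones were withdrawn for 24 h in charcoal-stripped medium, cells were treated for 6 h with ethanol or 1 µM dexamethasone, and stranded libraries were made from 300 ng of RNA with an integrity number of at least 8.6. Replicates came from 2 experiments with 2 transductions each, per the labels; which replicate number belongs to which experiment or transduction is not given in the sources used here.

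The authors deposited a table of raw read counts per gene, which had not been normalized. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20.0.422, trimmed with cutadapt 3.7, aligned with STAR 2.7.6a to GRCh38.p13 and counted with featureCounts 2.0.3. The strand setting of the counting, the treatment of multi-mapping reads and the annotation release are not given in the sources used here. Reads of near-identical genes may therefore be split or lost, which makes values of gene families such as metallothioneins, CYP3A genes and ORM1 with ORM2 uncertain, and antisense or overlapping genes are uncertain as well. The table held 60683 genes, of which 37960 had a count; symbols were those paired with Ensembl identifiers in the table, and list members were matched by identifier through a table of gene names, which matched all 459 entries of the lists. No coordinates were used here.

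Samples were grouped by the titles in the labels. Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3: genes were kept by filterByExpr with the 6 groups (16196 genes), libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 24 libraries without a replicate block. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The 10 contrasts were the dexamethasone response in each genotype, the 3 differences of these responses, and the levels of K154R and K154Q against WT within each treatment. CPM values are scaled by the TMM factors, and ± marks the SD of 4 libraries. SE was worked back from the test, as the absolute fitted log2 fold change divided by the root of the quasi-likelihood F. It is uncertain for genes with few counts, and 95% intervals of single-gene log2 differences use it. At these library sizes the spread between replicates, not counting error, limits the precision for well-expressed genes: chi-square per degree of freedom between replicates was at least 12.5, so no pair of replicates differed by as little as sampling noise. For genes with 0 vehicle counts a fold is a lower bound against a floor of 3 counts over the group, and counting intervals are exact 95% binomial intervals; both cover counting error only.

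Design, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. For each response the rule took the 10 genes with the largest positive and the 6 with the largest negative log2 fold change among called genes with a mean of at least 5 CPM over the 8 libraries and all 4 dexamethasone libraries beyond all 4 vehicle libraries. For each contrast between genotypes it took the 6 called genes with the smallest p in each direction and a mean of at least 5 CPM, and for each list up to 4 measured members with the smallest p. NR3C1 was always named, and identifiers without a symbol were skipped. Genes named outside the rule are marked as chosen after their values were seen. The 23 lists, of which some share members, were tested with camera at a preset correlation of 0.01, adjusted over lists within a contrast, and again with an estimated correlation. Response size was compared with fry over genes with an average log2 fold change of at least 1. The target score is the mean log2 CPM (prior count of 2) over the 25 measured members of the glucocorticoid-induced target list, compared with exact permutation tests; intervals of its differences come from a linear model with the 6 groups. No list was chosen on these samples by the study, as far as the labels say.

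Whether replicate numbers pair libraries was checked from the correlation of deviations from group means over all tested genes. Of 60 same-number pairs across groups 55 had r over 0.1 (median 0.347, against -0.126 for different numbers), and 23 of 24 libraries varied most closely with their own number. Every same-number pair exceeded 0.1 for the responses in K154R (lowest r 0.264) and K154Q (0.381), their difference (0.183), and the vehicle contrasts of K154R (0.310) and K154Q (0.306) with WT. For these, results of a fit with the replicate number as a block are given where they change a call. For the others the numbers were not taken to pair libraries.

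Alternatives were RLE size factors, no filter, DESeq2 1.42.0, the replicate block, a block within each genotype, fits of only the groups compared, leaving out each library in turn, and others for scores and lists. The code was tested on simulated counts drawn from the real means and library sizes with 200 changed genes: of genes changed 1.5-fold, 2-fold and 4-fold in WT, 61.2%, 97.0% and 100% were found, with 5 false calls. These counts held no variation shared by replicate number. Changed genes were drawn only from genes above a minimum mean CPM, so the shares do not cover genes with few counts. In the fit without a block and with the filter, the contrasts that share WT libraries called 0 genes, so no overlap of calls between them was computed. Figures were drawn with matplotlib 3.10.9.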

Results

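Gene expression was measured by poly(A) RNA sequencing in HepG2 cells, a human hepatocellular carcinoma line, in which the glucocorticoid receptor gene NR3C1 had been disrupted and a tagged receptor put back by doxycycline-inducible lentiviral expression. The receptor put back was wild type (WT), K154R, in which a lysine is replaced by an arginine that cannot be acetylated, or K154Q, in which a glutamine mimics the acetylated lysine. Cells of each genotype received ethanol vehicle or 1 µM dexamethasone, a synthetic glucocorticoid, for 6 h. Each of the 6 groups held 4 biological replicates, drawn per the labels from 2 independent experiments with 2 independent transductions each, which gave 24 libraries. Library totals ran from 23863672 counts in K154R vehicle replicate 4 to 42072021 in K154R vehicle replicate 1, and between 23420 and 25659 genes had at least 1 count. Messenger RNA of the mitochondrial genome took 5.16% of the counts in WT vehicle replicate 4 (exact 95% binomial interval 5.15% to 5.17%) and 9.16% in K154R dexamethasone replicate 2 (9.15% to 9.17%), the lowest and the highest of the 24 libraries.

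The transcript of the receptor, NR3C1 (ENSG00000113580), was compared between the groups first. Doxycycline had been adjusted to match receptor protein, per the labels. NR3C1 stood at 93.1 ± 14.4 CPM (SD, n = 4) in WT vehicle libraries, 88.0 ± 11.9 in K154R and 86.8 ± 12.2 in K154Q, and at 88.3 ± 14.2, 83.4 ± 10.1 and 87.6 ± 13.5 CPM after dexamethasone. On the log2 scale the vehicle level differed from WT by -0.08 (SE 0.14) in K154R and -0.10 (SE 0.14) in K154Q, and dexamethasone moved the transcript by -0.08 in WT, -0.08 in K154R and 0.01 in K154Q. None of these differences exceeded the spread between replicates (edgeR adjusted p of 1.0 for each, 95% interval of the vehicle difference -0.36 to 0.20 for K154R and -0.38 to 0.18 for K154Q). Gene counts cannot separate the introduced receptor from transcripts of the disrupted endogenous gene, and they do not show the replaced residue, so this comparison did not check the genotype labels.

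**Figure D1:**
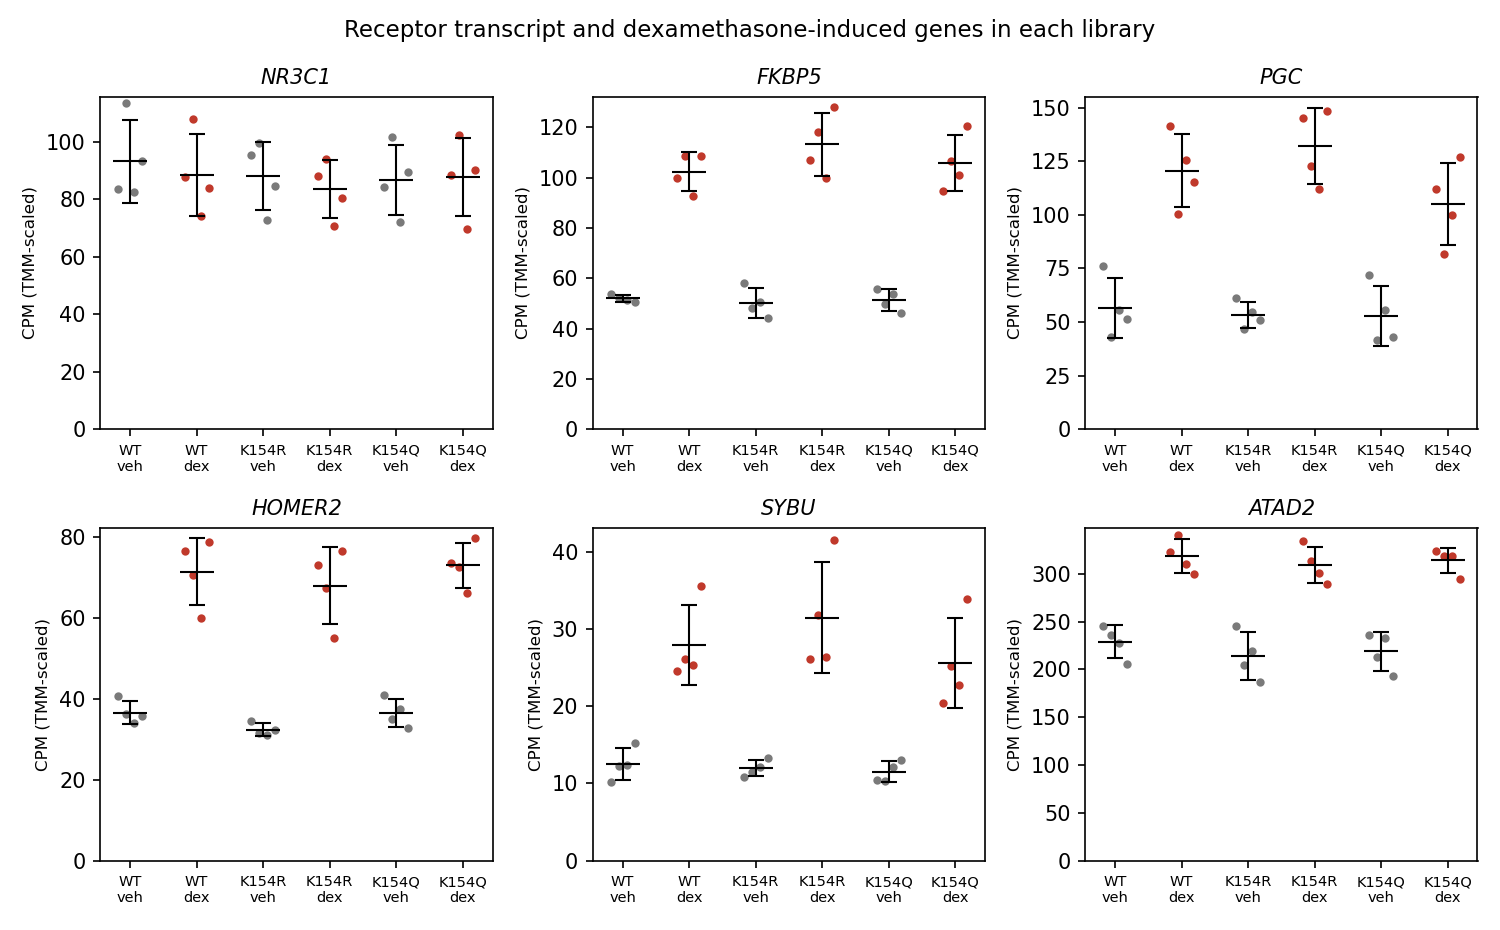
CPM values (counts scaled to library size with TMM factors) of NR3C1 and of 5 dexamethasone-induced genes in each of the 24 libraries, with vehicle libraries in grey and dexamethasone libraries in red; bars show the mean and SD of 4 libraries. NR3C1 group means lie between 83.4 and 93.1 CPM, while every dexamethasone library lies above every vehicle library of its genotype for FKBP5, PGC, HOMER2, SYBU and ATAD2. The rule for named genes required this separation, so it is not a separate result.

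The response to dexamethasone was examined in each genotype in turn. In WT cells, dexamethasone raised FKBP5 (ENSG00000096060), which encodes a co-chaperone of steroid receptors and is a classical receptor target, from 52.1 ± 1.44 to 102 ± 7.68 CPM (log2 fold change 0.98, SE 0.09, adjusted p = 3.3e-06, n = 4 per group). HOMER2, a scaffold protein gene, rose by 0.97 (SE 0.10), PGC, which encodes pepsinogen C, by 1.09 (SE 0.17), and SYBU, which encodes syntabulin, by 1.16 (SE 0.16). CRY2, a circadian repressor, rose by 0.50 (SE 0.09), and EMP2, an epithelial membrane protein gene, rose by 0.69 (SE 0.12). Several induced genes were scarcely expressed in vehicle. PDK4, an inhibitory kinase of pyruvate dehydrogenase, had 0 counts over the 4 vehicle libraries and 57 after dexamethasone, at least 20.7-fold higher against a floor of 3 counts over the group. HIF3A, a hypoxia-inducible factor gene, had 1 and 77 counts, a ratio of 84.1 with a 95% counting interval of 14.6 to 3364. Among genes chosen after their values were seen, PNMT, the adrenaline-synthesizing enzyme, rose by 5.04 (SE 0.50), UPP2, a uridine phosphorylase, by 3.17 (SE 0.38), and KCNH2, a potassium channel gene, by 2.82 (SE 0.38).

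In all, edgeR's quasi-likelihood test called 26 genes higher and 0 lower in WT out of 16196 tested at an adjusted p under 0.05, with 522 genes at an unadjusted p under 0.05. DESeq2 called 55 higher and 0 lower, and edgeR with no filter on low counts 77 higher and 1 lower. Replicate numbers were not taken to pair the WT libraries, so the larger WT count with a replicate block is given in the part on processing. Blocked counts of K154R and K154Q are to be set against that count, not against 26. Of the other genes named by the fixed rule, ATAD2, a bromodomain ATPase gene, rose by 0.48 (SE 0.08). Its call was lost without WT vehicle replicate 4 (adjusted p = 0.052) and when only the WT libraries were fitted (adjusted p = 0.0740). STOM, a membrane protein gene, rose by 0.68 (SE 0.12), a call lost without WT vehicle replicate 1 (adjusted p = 0.090). NAGS, which makes the activator of the urea cycle's first enzyme, rose by 0.76 (SE 0.15), a call lost without WT vehicle replicate 1 or 2 or dexamethasone replicate 4, with an adjusted p of up to 0.149. Calls for FLVCR2 (0.76, SE 0.15), ANGPTL4 (1.35, SE 0.28), an inhibitor of lipoprotein lipase, and TSC22D3 (3.32, SE 0.68), which encodes the glucocorticoid-induced leucine zipper, were lost without any of 6, 6 and 5 of the 8 WT libraries, with adjusted p of up to 0.182, 0.434 and 0.261. The adjusted p of ANGPTL4 was 0.233 when only the WT libraries were fitted.

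In K154R cells, FKBP5 rose from 50.2 ± 5.91 to 113 ± 12.4 CPM (log2 1.17, SE 0.09, adjusted p = 9.0e-08, n = 4 per group). SYBU rose by 1.40 (SE 0.16), PGC by 1.31 (SE 0.17), NAGS by 1.11 (SE 0.15) and HOMER2 by 1.07 (SE 0.10). TFEB, a regulator of lysosomal genes, rose by 0.97 (SE 0.14), CRY2 by 0.76 (SE 0.09) and ATAD2 by 0.53 (SE 0.08). PNMT rose by 4.60 (SE 0.44), UPP2 by 2.90 (SE 0.37), KCNH2 by 3.72 (SE 0.39) and HIF3A by 4.04 (SE 0.59). edgeR called 50 genes higher and 0 lower, with 517 at an unadjusted p under 0.05. DESeq2 called 74 higher and 3 lower, and edgeR with no filter 107 higher and 2 lower. The count fell to 31, 28, 33 and 23 genes without K154R vehicle replicate 2 or 3 or dexamethasone replicate 2 or 4 respectively, and to 26 when only the K154R libraries were fitted. WT and K154Q had 22 and 16 calls when fitted by themselves. CAVIN2, a caveolar protein gene (1.03, SE 0.20), CEBPD, a C/EBP transcription factor gene (1.07, SE 0.22), CCDC68 (0.91, SE 0.19), FLVCR2 (0.80, SE 0.15) and TSC22D3 (3.03, SE 0.60) lost their calls without any of 3, 5, 5, 3 and 4 of the 8 K154R libraries, with adjusted p of up to 0.0794, 0.159, 0.141, 0.0680 and 0.159. PDK4, with 2 vehicle and 60 dexamethasone counts (ratio 33.1, counting interval 8.77 to 280), lost its call without vehicle replicate 1 or dexamethasone replicate 4 (adjusted p of up to 0.0821). When only the K154R libraries were fitted, the calls for PDK4, ATAD2 and TSC22D3 were lost, with adjusted p of 0.121, 0.0945 and 0.0755.

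Libraries of the same replicate number varied together in K154R and in K154Q. With the replicate number as a block edgeR called 190 genes higher and 10 lower in K154R, among them all 50 genes called without the block. The blocked fit also called 3 genes named here that the fit without it did not: NSDHL, a sterol-synthesis enzyme gene (log2 0.54, adjusted p = 6.4e-05; 0.53 and adjusted p = 0.502 without the block), PER1, a clock gene (0.60, adjusted p = 5.3e-04; 0.59 and 0.130, or 0.0372 by DESeq2), and ANGPTL4 (1.00, adjusted p = 0.0039; 1.03 and 0.204).

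In K154Q cells, FKBP5 rose from 51.3 ± 4.24 to 106 ± 11.1 CPM (log2 1.04, SE 0.09, adjusted p = 9.4e-07, n = 4 per group). SYBU rose by 1.16 (SE 0.16), HOMER2 by 1.00 (SE 0.10), NAGS by 0.90 (SE 0.15), CRY2 by 0.67 (SE 0.09) and ATAD2 by 0.52 (SE 0.08). PNMT rose by 3.28 (SE 0.41), UPP2 by 3.31 (SE 0.41) and KCNH2 by 3.23 (SE 0.40). HIF3A had 2 vehicle and 81 dexamethasone counts, a ratio of 36.5 with a counting interval of 9.78 to 306. edgeR called 21 genes higher and 0 lower, with 366 at an unadjusted p under 0.05. DESeq2 called 46 higher and 1 lower, and edgeR with no filter 71 higher and 1 lower. With the replicate number as a block, edgeR called 114 higher and 3 lower, among them all 21. Calls for PGC (0.99, SE 0.17) were lost without vehicle replicate 2 or 4 or dexamethasone replicate 4, with an adjusted p of up to 0.0660. TFEB (0.70, SE 0.14) and PDK4, with 2 and 59 counts (ratio 26.6, counting interval 7.04 to 224), lost theirs without any of 5 and 7 of the 8 K154Q libraries, with adjusted p of up to 0.245 and 0.207. When only the K154Q libraries were fitted, the calls for PGC and TFEB were lost, with adjusted p of 0.105 and 0.254. TSC22D3 stood at 2.42 (SE 0.63, adjusted p = 0.235) and was called with the block (2.34, adjusted p = 3.0e-04) and by DESeq2 (adjusted p = 0.0218). NSDHL, PER1 and ANGPTL4 stood at 0.41, 0.54 and 0.85 with adjusted p of 1.0, 0.328 and 0.878, and were called with the block (adjusted p = 0.0028, 0.0021 and 0.026).

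The genes called in at least 1 genotype numbered 52, and all 52 had a positive log2 fold change in all 3. Genes called in all 3 numbered 17, among them FKBP5, PGC, SYBU, HOMER2, NAGS, CRY2, ATAD2, PDK4, HIF3A, PNMT, UPP2 and KCNH2. K154R and WT shared 24 called genes, K154Q and WT 17, and K154Q and K154R 21, where independent lists of these sizes would share 0.080, 0.034 and 0.065. These responses share no libraries, but the same fit gives them a shared estimate of each gene's spread, so the lists are not fully independent. CYP3A43, whose family holds near-identical genes that may share reads, and ANGPTL4 were called in WT alone, 22 genes in K154R alone and 0 in K154Q alone. Being called in 1 genotype is not a difference between genotypes, which was tested separately. Across the 52 genes, which are not independent replicates, log2 fold changes in WT correlated with those in K154R (Pearson r = 0.950, Spearman rho = 0.965) and in K154Q (0.948 and 0.966).

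**Figure D2:**
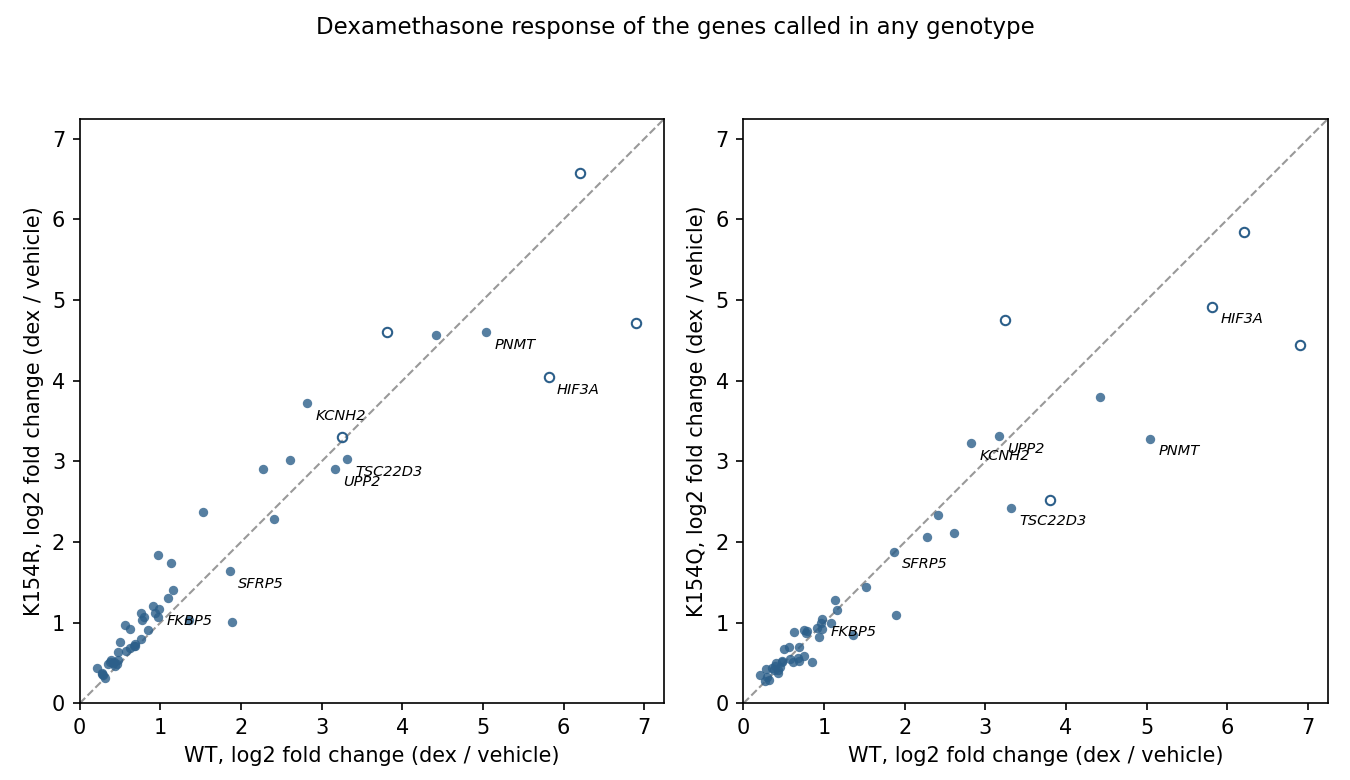
Log2 fold change of dexamethasone over vehicle in WT (x axis) against K154R (left, y axis) and K154Q (right, y axis) for the 52 genes called in at least 1 genotype; each point is a gene, the dashed line marks equal values, and open circles mark genes with at most 3 counts over the vehicle libraries of a genotype, whose fitted values depend on the prior count. All points lie above 0 on both axes, and PNMT lies at 5.04 in WT, 4.60 in K154R and 3.28 in K154Q.

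Whether the exchange of the lysine changed the response was asked by testing the difference of the responses. For FKBP5 the log2 response in K154R minus that in WT was 0.19 (SE 0.13, unadjusted p = 0.149). For DUSP1, a phosphatase gene induced by glucocorticoids, the difference from WT was 0.39 (SE 0.23) in K154R and 0.31 (SE 0.23) in K154Q. PNMT, chosen after its values were seen, had a difference of -1.75 (SE 0.76, unadjusted p = 0.029) for K154Q minus WT. All of these had an adjusted p of 1.0. edgeR called 0 genes for K154R minus WT, K154Q minus WT and K154Q minus K154R, with 115, 145 and 99 genes at an unadjusted p under 0.05, and DESeq2 called 0, with 84, 126 and 86. The edgeR numbers are 0.71%, 0.90% and 0.61% of the genes tested, while unchanged genes would on average give a share of about 0.05. The fit without a block was therefore conservative, and its 0 calls do not exclude differences. With the replicate number as a block K154Q minus K154R, whose libraries pair, also had 0 calls, with 286 genes at an unadjusted p under 0.05. These are 1.77% of the genes tested, so the blocked fit was conservative here as well. In simulated data with known differences, the test of K154R minus WT found 38.8% of genes whose responses differed 1.5-fold, 86.6% of those 2-fold apart and 98.5% of those 4-fold apart. The simulated counts held no variation shared by replicate number, and changed genes were drawn only from those above a minimum mean CPM. These shares hold for such data only and do not cover genes with few counts. For PDK4 and HIF3A the difference of the K154R response from WT had an SE of 1.83 and 1.27.

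The size of the response was also compared over 36 genes called in the average over the genotypes with a log2 fold change of at least 1. Their median log2 fold change was 1.68 in WT, 1.85 in K154R and 1.497 in K154Q. PDK4, FRMPD1, CES4A, PPP1R1B and HIF3A, with at most 3 vehicle counts in a genotype, lay above these medians at their bounds as well, so the medians stay as they are. The median difference was 0.18 for K154R minus WT, -0.14 for K154Q minus WT and -0.27 for K154Q minus K154R. Without 1 library these ranged from 0.08 (without K154R dexamethasone replicate 4) to 0.38 (without WT dexamethasone replicate 4), from -0.37 (without K154Q dexamethasone replicate 4) to -0.05 (without K154Q dexamethasone replicate 3), and from -0.55 (without K154Q dexamethasone replicate 4) to -0.18 (without K154R dexamethasone replicate 4). limma's fry test gave these differences an adjusted p of 0.664 each, with unadjusted values of 0.664, 0.595 and 0.337. With no minimum fold change the difference of K154Q from WT changed sign, to 0.0092. For the mean log2 CPM of these genes, the response in K154R minus that in WT was 0.11, with a 95% interval of -0.39 to 0.62. For K154Q minus WT it was -0.17, with an interval of -0.68 to 0.34. For K154Q minus K154R, whose libraries pair by number, it was -0.28, with an interval of -0.79 to 0.22. Neither this interval nor the fry values above used that pairing.

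Glucocorticoid-induced target genes, a list of 28 symbols fixed in advance with 25 measured members, rose in each genotype (camera adjusted p = 1.5e-25 in WT, 1.8e-33 in K154R and 1.2e-28 in K154Q). These calls held with an estimated correlation between genes, with adjusted p of 1.7e-04, 4.0e-05 and 1.1e-04. In WT 5 members passed the test over all genes (FKBP5, PDK4, TSC22D3, ANGPTL4 and HIF3A) and 11 when adjusted over the list alone. In K154R 6 members passed (FKBP5, PDK4, TSC22D3, HIF3A, CAVIN2 and CEBPD) and 13 when adjusted over the list alone. In K154Q 3 members passed (FKBP5, PDK4 and HIF3A) and 10 when adjusted over the list alone. The fit with the replicate number as a block called 14 members over all genes in K154R and 11 in K154Q, all higher. No member passed as lower in any genotype. The mean log2 CPM of the list rose from 2.86 ± 0.09 to 3.51 ± 0.14 in WT, from 2.92 ± 0.09 to 3.57 ± 0.19 in K154R and from 2.91 ± 0.09 to 3.49 ± 0.17 in K154Q, with every dexamethasone library above every vehicle library of its genotype (exact two-sided permutation p = 0.0286 each, the smallest that 4 against 4 libraries can give).

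Differences of the target score between genotypes did not pass the test. After dexamethasone it differed by 0.06 for K154R minus WT (exact permutation p = 0.6), -0.03 for K154Q minus WT (p = 0.771, exact) and -0.08 for K154Q minus K154R (p = 0.571, exact). In vehicle it differed by 0.06 (exact p = 0.4), 0.05 (exact p = 0.457) and -0.02 (exact p = 0.771), and the adjusted values lay between 0.686 and 0.771. Between libraries of the same number, K154R minus WT in vehicle was positive in 4 of 4 pairs (0.03 to 0.08), and K154Q minus K154R after dexamethasone was negative in 4 of 4 (-0.17 to -0.03). The exact two-sided sign-flip p was 0.125 for each, the smallest that 4 pairs can give, so pairs could not reach the threshold. The response itself differed by -0.005 for K154R minus WT, with a 95% interval of -0.29 to 0.28, and by -0.07 for K154Q minus WT, with an interval of -0.35 to 0.21. For K154Q minus K154R, whose libraries pair by number, the response differed by -0.07, with an interval of -0.35 to 0.21. These intervals did not use replicate numbers. Signs of these small differences turned when 1 library was left out: the dexamethasone difference of K154R from WT was -0.02 without K154R dexamethasone replicate 4, and that of K154Q from WT was 0.04 without WT dexamethasone replicate 4 and 0.01 without K154Q dexamethasone replicate 1. The vehicle difference of K154Q from K154R was 0.02 without K154R vehicle replicate 4, and 0.002 and 0.009 without K154Q vehicle replicates 1 and 3. With the median over members in place of the mean, the vehicle differences from WT turned to -0.05 in K154R and -0.16 in K154Q.

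**Figure D3:**
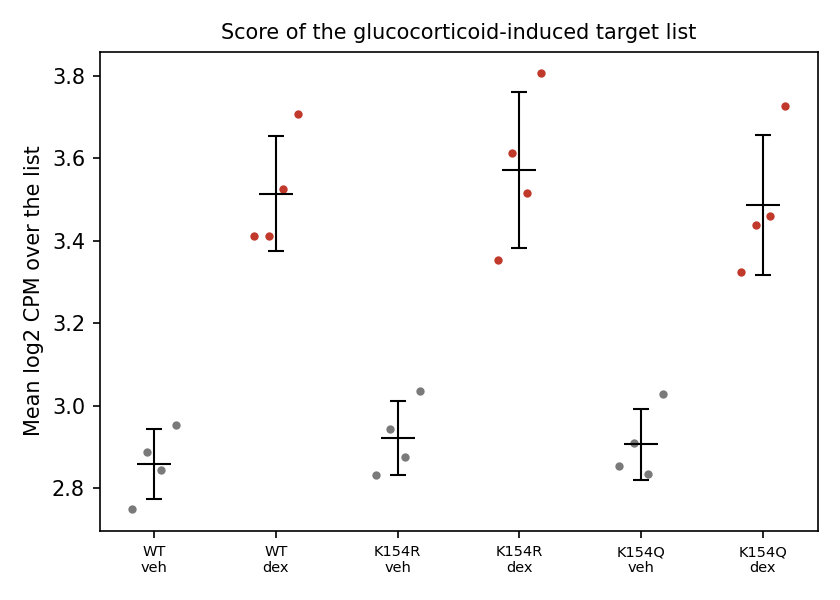
Mean log2 CPM over the 25 measured members of the glucocorticoid-induced target list in each of the 24 libraries, with vehicle libraries in grey and dexamethasone libraries in red; bars show the mean and SD of 4 libraries, and the y axis does not start at 0. Group means lie between 2.86 and 2.92 in vehicle and between 3.49 and 3.57 after dexamethasone.

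Genes of cholesterol synthesis had positive fold changes in 22 of 23 members in WT, 22 in K154R and 21 in K154Q, with median log2 fold changes of 0.15, 0.11 and 0.14 (camera adjusted p = 6.1e-05, 0.0028 and 0.0020). Without the replicate block none passed the test by itself, over all genes or adjusted over the list alone. The block called 1 of the 23, NSDHL, as higher in K154R and in K154Q, as given above. NSDHL stood at 0.47 (SE 0.17) in WT. Proteasome subunit genes had negative fold changes in 31 of 32, 29 and 29 members, with medians of -0.08, -0.05 and -0.07 (adjusted p = 4.9e-04, 0.031 and 0.0029). Genes of the unfolded protein response leaned upward in WT and K154R (medians 0.10 and 0.06, adjusted p = 0.0048 and 0.031). No proteasome or unfolded protein response gene passed by itself without the block either. In K154R the block called 1 of the 17 unfolded protein response genes as higher. None of these list calls held with an estimated correlation. The adjusted p was then 0.645, 0.857 and 0.879 for cholesterol synthesis, 0.675, 0.857 and 0.927 for the proteasome, and 0.439 and 0.857 for the unfolded protein response. In K154Q the circadian clock list leaned upward (adjusted p = 0.049), with CRY2 as the member that passed over all genes and 2 members adjusted over the list alone. Its adjusted p was 0.871 with an estimated correlation, 0.061 with the replicate block and 0.0545 with RLE size factors. Metallothionein genes, whose adjusted p in K154R was 0.202, leaned upward there with the replicate block (adjusted p = 0.0063), a call lost when the block was combined with an estimated correlation (adjusted p = 0.514 with an estimated correlation). Of the 6 measured metallothionein genes, 2 passed over all genes as higher in K154R with the block.

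In WT, cell cycle genes leaned downward (25 of 27 members, median -0.10, adjusted p = 1.1e-05) and genes of xenobiotic and bile acid metabolism upward (median 0.13, adjusted p = 6.4e-04), CYP3A5 standing at 0.48 (SE 0.15, adjusted p = 0.586 over all genes). All 13 mitochondrially encoded messenger RNAs, listed as a sign of RNA quality, leaned upward with them (median 0.27, adjusted p = 4.8e-09), their share of counts being 7.04 ± 1.28% in WT vehicle and 8.33 ± 0.35% in WT dexamethasone libraries (n = 4). No member of these lists passed by itself, over all genes or adjusted over the list alone. These calls too were lost with an estimated correlation (adjusted p = 0.595, 0.257 and 0.400). The mitochondrial share was 7.92 ± 0.59% and 7.89 ± 1.13% in K154R vehicle and dexamethasone libraries, and 7.16 ± 1.09% and 7.29 ± 0.84% in those of K154Q. For the difference of responses, the same 13 genes had medians of -0.28 for K154R minus WT and -0.22 for K154Q minus WT (camera adjusted p = 1.7e-10 and 2.3e-06). Cell cycle genes had medians of 0.06 and 0.07 (adjusted p = 0.040 and 0.0072). With an estimated correlation the adjusted p was 0.810 and 0.990, and 0.983 and 0.990. Without WT vehicle replicate 4, the library with the lowest mitochondrial share, the cell cycle list was not called for K154R minus WT (adjusted p = 0.062), nor was the mitochondrial list for K154Q minus WT (adjusted p = 0.315).

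The other fixed lists were not called in any dexamethasone response with all 24 libraries. Without WT vehicle replicate 4, those of gluconeogenesis (adjusted p = 0.0036) and fatty acid oxidation (adjusted p = 0.0070) were called in WT. Neither call held there with an estimated correlation (adjusted p = 0.699 and 0.482 with an estimated correlation). Camera adjusted p in WT, K154R and K154Q was 0.526, 0.284 and 0.351 for gluconeogenesis and amino acid catabolism, where the classical target TAT stood at 0.41 (SE 0.29) in WT, and 0.879, 0.473 and 0.854 for NF-kB and inflammatory genes. The values were 0.386, 0.892 and 0.903 for acute-phase proteins, 0.718, 0.682 and 0.316 for fatty acid and triglyceride synthesis, and 0.191, 0.284 and 0.0624 for fatty acid oxidation. The fatty acid oxidation list had a median of -0.04 in WT but a positive mean and an upward test. Median, mean and test also differed in sign in WT for the NF-kB, hepatocyte identity, circadian and endothelial lists, in K154R for the interferon, hypoxia and circadian lists, and in K154Q for the gluconeogenesis, HSP90 and acetyltransferase lists. Hepatocyte identity genes gave 0.526, 0.284 and 0.168, interferon response genes 0.526, 0.682 and 0.854 and HSP90 chaperone genes 0.542, 0.986 and 0.854. The p53 targets gave 0.526, 0.682 and 0.854, hypoxia and glycolysis genes 0.718, 0.559 and 0.859, and lysine acetyltransferases and deacetylases 0.403, 0.473 and 0.854. Markers of other cell types, each list with 3 measured members, gave 0.526, 0.516 and 0.661 for fibroblasts, 0.526, 0.559 and 0.661 for leukocytes and 0.718, 0.996 and 0.661 for endothelial cells. The leukocyte list summed to 736 ± 184 CPM in WT vehicle libraries (n = 4), and which cells expressed its members was not tested.

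Levels were then compared between genotypes within a treatment. Doxycycline doses were set to match receptor protein, and the dose of each group is not given in the sources used here. If doses differed between genotypes, differences of level cannot be told apart from those of dose. In vehicle, edgeR called 0 genes for K154R minus WT (221 at an unadjusted p under 0.05) and 0 for K154Q minus WT (165), and DESeq2 called 0 for each (199 and 131). The edgeR numbers are 1.36% and 1.02% of the genes tested, again under a share of 0.05. Libraries of these groups paired by replicate number, and with that number as a block 4 genes were called in each contrast, chosen here after their values were seen. Both contrasts use the same WT vehicle libraries, so a call in both is not independent. PKIB, a protein kinase A inhibitor gene, stood at 1.82 ± 0.746 CPM in WT, 0.706 ± 0.507 in K154R and 0.560 ± 0.254 in K154Q vehicle libraries (blocked log2 difference -1.47, SE 0.25, and -1.71, SE 0.26; adjusted p = 0.018 and 0.0033). CD44, a cell surface glycoprotein gene, was called in both contrasts at 1.73 ± 1.99 CPM in WT against 0.0059 ± 0.012 in K154R and 0.0086 ± 0.017 in K154Q; within WT it stood at 3.48 ± 0.502 CPM in replicates 1 and 2 of both treatments and at 0.0163 ± 0.0192 in replicates 3 and 4. DKK1, a Wnt inhibitor gene, was higher in K154R (0.74, SE 0.12, adjusted p = 0.018), as was SORCS1, while in K154Q PTPRD was higher and C19orf38 lower. Over both treatments SORCS1 in K154R stood at 0 CPM in replicates 1 and 2 and 0.786 ± 0.263 in 3 and 4, and PTPRD in K154Q at 0.0118 ± 0.0236 and 5.07 ± 1.75 (n = 4 each), so these differences, like that of CD44, lay in 2 of the 4 replicates.

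After dexamethasone, edgeR called 0 genes for K154R minus WT (253 at an unadjusted p under 0.05) and 0 for K154Q minus WT (243), and DESeq2 called 0 (219) and 1 (245). The gene DESeq2 called was PKIB, lower in K154Q (log2 -2.45, adjusted p = 0.0089), and edgeR called PKIB too when only the 8 libraries compared were fitted (-2.44, adjusted p = 0.042). PKIB stood at 1.82 ± 0.489 CPM in WT and 0.335 ± 0.123 in K154Q dexamethasone libraries. In simulated data with known differences and no variation shared by replicate number, the vehicle contrast of K154R and WT found 64.2% of genes changed 1.5-fold and 97.0% of those changed 2-fold. Genes with few counts are not covered by these shares either.

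Some lists leaned between genotypes. Unfolded protein response genes (median 0.11, adjusted p = 0.015) and mitochondrially encoded genes (median 0.22, adjusted p = 3.6e-09) leaned upward in K154R against WT vehicle libraries, with positive differences in 14 of 17 and 13 of 13 members. After dexamethasone, proteasome (median 0.07, adjusted p = 0.0020) and HSP90 chaperone genes (0.07, adjusted p = 0.012) leaned upward in K154R against WT, with positive differences in 31 of 32 and 18 of 20 members, and acute-phase (-0.12, adjusted p = 0.024), xenobiotic (-0.08, adjusted p = 0.0092) and mitochondrially encoded genes (-0.21, adjusted p = 1.3e-07) leaned downward in K154Q against WT. No member of these lists passed the test by itself in these comparisons, over all genes or adjusted over the list alone. None of the calls held with an estimated correlation, where the adjusted p was 0.833 for both vehicle lists, 0.787 for the proteasome and HSP90 lists, and 0.456, 0.456 and 0.526 for the K154Q lists. Without WT vehicle replicate 4 the vehicle calls of K154R were lost (adjusted p = 0.081 and 0.218), the proteasome list was called as leaning upward there (adjusted p = 0.0019, or adjusted p = 0.816 with an estimated correlation), and the mitochondrial list as leaning downward in K154Q against WT vehicle libraries (adjusted p = 0.011, or adjusted p = 0.994 with an estimated correlation). With the replicate block, the cholesterol synthesis (adjusted p = 0.022), metallothionein (0.0024), proteasome (0.012) and HSP90 chaperone lists (0.0024) were also called as leaning upward in K154R against WT vehicle libraries, though no member of them passed over all genes. These calls too were lost when the block was combined with an estimated correlation (adjusted p = 0.771, 0.503, 0.771 and 0.771 with an estimated correlation).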

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

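The tests of sequencing depth, of single libraries, of low counts, of a shared experiment and of the overlap between genotypes were chosen after the results were seen; the scrambled blocks, the relabelled genotypes and the other splits of the libraries were set before their results were seen. Relabellings that kept numbers balanced were added after the other relabellings had been seen, but before their own result was.

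Of 160 groups of 4 values examined, 8 held a value far from the other 3, and chance alone gives about 1 in 20 such groups. The share of counts taken by the 10 most abundant genes was 10.5% in WT vehicle replicate 4 (exact 95% binomial interval 10.51% to 10.53%) and 13.3% to 13.6% in its group. WT dexamethasone replicate 4 had 25264 detected genes against 24017 to 24146, and SYBU stood there at 35.6 CPM against 24.5 to 26.2. HIF3A stood at 0.0279 CPM in WT vehicle replicate 3 and at 0 in the others, and CCDC68 at 9.37 CPM in K154R dexamethasone replicate 4 against 7.43 to 7.72. TSC22D3 stood at 3.83 CPM in that library against 0.929 to 1.31, UPP2 at 0.318 CPM in K154Q vehicle replicate 3 against 0.138 to 0.150, and ATAD2 at 294 CPM in K154Q dexamethasone replicate 4 against 319 to 324.

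Responses of the cell cycle list differed from WT in K154R (camera adjusted p = 0.0404) and K154Q (0.00715), and those of the mitochondrially encoded list too (1.7e-10 and 2.3e-06), with a preset correlation but not with an estimated correlation.

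K154R had the most called genes, 50 against 26 in WT and 21 in K154Q. When each genotype was fitted by itself, the counts lay closer together, with 26 in K154R, 22 in WT and 16 in K154Q. The libraries of K154R held 252.3 M counts in sum, against 258.4 M in WT and 251.9 M in K154Q, which argues against depth as the reason. A candidate explanation is counting near the threshold: 7 of 100 relabellings that kept numbers balanced, the real labels included, gave counts at least as far apart as the real range of 29, up to 33 (63 of 100, up to 750, for relabellings that did not). Dependence on 1 library may also account for it, since without K154R dexamethasone replicate 4 the count was 23. A stronger response of the K154R receptor stays open as a biological explanation, with 0 calls for the difference of the responses. Over 36 genes the median difference from WT was 0.18 (limma's fry test, unadjusted p = 0.664). It ranged from 0.08 (without K154R dexamethasone replicate 4) to 0.38 (without WT dexamethasone replicate 4). The response of the target score differed by -0.005 for K154R minus WT, with an interval of -0.29 to 0.28. That interval, from a model without the replicate number, holds differences of either sign, so the score does not decide the question.

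With the replicate number as a block the 3 responses had 445 calls in sum, against 97 without it. Blocks of numbers scrambled within each group, which use as many residual degrees of freedom, gave a median of 87 calls over 39 draws, which argues against fewer degrees of freedom as the reason. Variation shared by libraries of the same number is a candidate explanation, since 1 of 40 blocks, the real numbers, reached 445 and the highest scrambled block gave 122. Whether the shared variation comes from the experiment, the transduction or the handling was not tested, and no biological explanation was tested.

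A total of 9 genes were on in 2 replicate numbers (a mean of at least 0.5 CPM and at least 0.25 in each library) and off in the other 2 (a mean of at most 0.1) within a genotype, 6 in WT, 2 in K154R and 1 in K154Q, always with numbers 1 and 2 set against 3 and 4. CD44 stood at 3.48 ± 0.502 CPM in WT numbers 1 and 2 and 0.0163 ± 0.0192 in 3 and 4 (n = 4 each, both treatments), and PTPRD at 0.0118 ± 0.0236 and 5.07 ± 1.75 in K154Q. Low counts as the reason are argued against by 0 such genes in the 2 other ways of pairing the numbers, and an experiment or day shared by the genotypes, as the cause for all of these genes, by 1 of the 9 being 4-fold apart, with 0.1 CPM added to both means, the same way in another genotype: ENSG00000287899 stood at 5.14 ± 0.883 CPM in WT numbers 3 and 4 against 0.0964 ± 0.0731 in 1 and 2 and at 2.23 ± 0.453 against 0.217 ± 0.142 in K154Q, but at 0.0618 ± 0.0425 against 0.297 ± 0.0819 in K154R, which goes against a cause shared by all 3. For FXYD1, under 4-fold apart even in WT with 0.1 CPM added to both means, a shared cause stays open, since it stood at 0.626 ± 0.239, 0.428 ± 0.0843 and 0.451 ± 0.203 CPM in numbers 3 and 4 of WT, K154R and K154Q against 0.0957 ± 0.0477, 0.148 ± 0.0923 and 0.232 ± 0.0877 in 1 and 2. Separately transduced cell pools with different founder cells could give such a pattern and were not tested, since the labels do not tie numbers to transductions. Over all genes the division was not the same in every genotype. With treatment in the model, edgeR called 236, 49 and 283 genes between numbers 1 and 2 and the other 2 in WT, K154R and K154Q. For numbers 1 and 3 against the other 2 it called 0, 22 and 961, and for 1 and 4 it called 0, 2 and 0.

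Other splits of the libraries were compared with the real ones. In K154R and K154Q, where numbers pair libraries, the 8 splits that part all same-number pairs, which differ by swapping treatment within some pairs, are too few for a share under 0.05; the real splits gave 50 and 21 calls and the 7 others 0. Over all 35 splits, which mostly break the pairs, the real one was 1 of 35 in each, with at most 14 and 5 calls in others. In WT 2 of 35 splits gave at least 26 calls, so by this count alone chance cannot be excluded; the other, with 49 calls, set replicates 1 and 2 of both treatments against 3 and 4, and the count with the replicate block was 128. Calls made by chance are argued against by the overlap between genotypes: 24 of the 26 genes called in WT were also called in K154R and 17 in K154Q, where independent lists would share 0.080 and 0.034, and all 21 genes called in K154Q were called in K154R. The responses share no libraries, and same-number libraries of different genotypes correlated no more within a treatment (median r 0.334 over 24 pairs) than across treatments (0.350). The responses do share the estimate of each gene's spread in the same fit, so the lists are not fully independent.

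For comparisons with 0 calls, a count of regroupings decides nothing, since each gives at least 0: all 35 splits did for the 4 comparisons of levels between genotypes, with at most 1 call in others, and all 100 relabellings for the 3 differences of responses. Relabellings within each treatment, which do not keep replicate numbers balanced, gave any call in 2, 5 and 0 of 100 for K154R minus WT, K154Q minus WT and K154Q minus K154R, with at most 1893, 510 and 0 calls, which points to a structure of the samples. Relabellings that kept the numbers balanced gave 0 calls in all 100 for each difference.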

How the results depend on the processing

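Fits without WT dexamethasone replicate 4, list tests without WT vehicle replicate 4, list tests with an estimated correlation in that setting or with the block, and list tests on the averaged response, which called 8 lists, were chosen after seeing the data; the other alternatives were planned. RLE size factors changed no count of genes by over 1.5 times, and the 3 differences of responses kept 0 calls in every alternative. Calls of dexamethasone responses in WT, K154R and K154Q rose to 78, 109 and 72 with no filter on low counts, 55, 77 and 47 with DESeq2, 128, 200 and 117 with the replicate block, 208, 296 and 184 with a replicate block within each genotype, and 108, 220 and 132 with the replicate block without WT dexamethasone replicate 4; K154R had 26 when only its groups were fitted and 23 to 61 without 1 library. For levels of K154R and K154Q against WT, calls were 15 and 14 in vehicle and 8 and 18 after dexamethasone with no filter, 4 and 4, and 2 and 5, with the replicate block, and 7 and 4, and 2 and 3, with it and without WT dexamethasone replicate 4; K154Q after dexamethasone had 1 by DESeq2 and 1 when only its groups were fitted. The cause was not tested, except that scrambled blocks bear on the replicate block.

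For contrasts whose numbers do not pair libraries (the WT response, its differences from K154R and K154Q, and levels after dexamethasone), same-number r was as low as -0.0459. WT dexamethasone replicate 4 alone did not correlate best with its own number. Genes called with the block after dexamethasone were PKIB and CD44 for K154R, and these with KIAA0319, PTPRD and C19orf38 for K154Q. Lists called with the replicate block numbered 6 for vehicle and 7 for dexamethasone levels of K154R against WT, the latter adding target genes (adjusted p = 0.0033), metallothioneins (4.9e-04), unfolded protein response genes (0.0103), p53 targets (0.0103) and, leaning downward, mitochondrially encoded genes (0.0324), where the block with an estimated correlation gave an adjusted p of 0.194, 0.248, 0.703, 0.703 and 0.784. In the WT response the block called metallothioneins (adjusted p = 0.014, or 0.379 with an estimated correlation) and NSDHL (5.6e-04), and for K154Q after dexamethasone PKIB (2.3e-05). The block also called 10 of the 25 measured target genes as higher over all genes in the WT response. It changed no other call of a named gene or list beyond those given here and in the results.

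With an estimated correlation, 1 list stayed called in each response and 0 in every other contrast, with and without the replicate block or WT vehicle replicate 4. Without WT vehicle replicate 4, 1 list each was called for both differences of responses from WT and both vehicle contrasts, the mitochondrial list in K154Q against WT turning direction (adjusted p = 0.0108, or 0.994 with an estimated correlation). Shared calls with a log2 fold change of at least 1 numbered 15 for K154R and WT, 11 for K154Q and WT and 13 for K154Q and K154R.

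Some uncalled small differences reversed. The median response of K154Q minus WT was 0.00918 with no minimum fold change; the vehicle target score differed from WT by -0.0528 in K154R and -0.160 in K154Q with the median over members. Without 1 library, the score difference ranged from -0.0204 to 0.131 (dexamethasone, K154R minus WT), -0.106 to 0.0380 (K154Q minus WT) and -0.0559 to 0.0225 (vehicle, K154Q minus K154R). NR3C1 ranged from -0.181 to 0.0324 for the response in WT and -0.0692 to 0.110 in K154Q, from -0.135 to 0.0274 and -0.185 to 0.00733 for vehicle levels of K154R and K154Q against WT, and from -0.162 to 0.0229 and -0.0943 to 0.0918 after dexamethasone. The cause was not tested.

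For single genes named here, 871 alternatives kept direction and side of the threshold, 66 lost a call, 59 of them without 1 library, and 39 gained one; none reversed. Depth limits genes with few counts, such as PDK4 with 57 to 60 counts over 4 libraries.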

Other observations

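The tests in this part were chosen after the data were seen. Averaged over the 3 genotypes, dexamethasone raised 166 genes and lowered 6 of 16196 (edgeR, adjusted p under 0.05), and the 6 lower genes, are named after their values were seen. ANGPTL1, which encodes a secreted angiopoietin-like protein, fell by 0.35 on the log2 scale (SE 0.05, adjusted p = 2.6e-04), NR1H4, the bile acid receptor gene, fell by 0.32 (SE 0.07, adjusted p = 0.0095), and VAV3, an exchange factor gene, fell by 0.25 (SE 0.05, adjusted p = 0.0026). NEK2, a mitotic kinase gene, fell by 0.24 (SE 0.06), VSNL1, a calcium sensor gene, fell by 0.23 (SE 0.04), and NFE2L2, the regulator of antioxidant genes, fell by 0.16 (SE 0.04). Of the 25 target genes 13 passed over all genes in the average and 15 when adjusted over the list alone.

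Among fixed lists, the average called fatty acid oxidation genes (adjusted p = 0.045), where the median log2 fold change was -0.03 and 3 of 17 members passed as higher, so median and test differ in sign; its adjusted p was 0.668 with an estimated correlation. Genes of xenobiotic and bile acid metabolism had 2 of 15 members higher over all genes (median 0.11, adjusted p = 0.0024; adjusted p = 0.418 with an estimated correlation).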
